A study of Rattus norvegicus with 10 samples.

How the data were processed

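Total RNA from the right side of the brain, divided at the midline, was measured on 10 Affymetrix arrays. Each array carried RNA of 1 male Wistar rat aged 7 weeks, 5 rats that inhaled vapor of distilled water (control) and 5 that inhaled vapor of DMHF, a methylated hydroxyfuranone known as an aroma compound of strawberry and other foods. Per the labels' protocols, the RNA was extracted with ISOGEN II, cleaned on RNeasy columns and labelled with biotin by 3' in vitro transcription. Groups and replicate numbers came from the sample titles, which call the samples biological replicates. Litter, cage, array batch and scan date are not given in the sources used here.

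The authors deposited 1 table of processed values with 31099 probe sets and 1 column per array, and the scanner files were not used here. Per the submitters' processing notes, R 2.7.2 was used. The background correction, normalization and probe set summary method are not given in the sources used here. The deposited values ran from 5.25 to 14.22 and were taken as log2 expression values from that range, since the log base is not stated. The direction of the scale was taken as higher for more RNA. The deposited log2 values had a property that governs everything computed from them. The SD of a probe set over the 10 arrays had a median of only 2.20 millionths of a log2 unit, with a 5th percentile of 0.282, a 95th percentile of 18.9 and a maximum of 64983 millionths. Which step of the authors' processing left the differences between arrays this small, and whether it acted alike on every probe set, is not given in the sources used here. A difference is given here in millionths of a log2 unit of the deposited scale, cannot be turned into a fold change of RNA, and is comparable between arrays for a given probe set but not between probe sets. For that reason it is also given in units of the pooled within-group SD of the same probe set.

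The 57 Affymetrix control probe sets were left out of the tests, which left 31042 probe sets, none of them constant. Genes were named from GEO's platform annotation. Of the 31042 probe sets, 20826 named a single gene, 436 named several genes and were not used for naming, and 9780 are unnamed here. The gene identifiers of 20758 of the 20826 were found in the NCBI rat gene table of assembly GRCr8, which changed 0 symbols. For tests at gene level, the probe set with the highest mean over all arrays stood for the gene, which gave 14217 genes. No genome was used, so no coordinates are given.

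DMHF was compared with control for every probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 10 arrays, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene below is from this limma fit. The prior degrees of freedom were 0.841. For probe sets of small spread the moderated SE still lay well above what their own spread gives. A difference in within-group SD and its p therefore need not rank alike: Cbarp at 7.00 SD had a moderated t of 6.45 and Rpa1 at -3.99 SD of -6.60. Gene lists were fixed before the data were examined, 18 by function and 20 for cell types, brain regions and neighbouring tissues. They named 604 distinct genes, of which 516 were measured at gene level here. The 38 lists, all with at least 5 measured genes, were tested together with limma's camera at its preset correlation of 0.01. They were also tested with an estimated correlation, with fry, and by an exact two-sided permutation test of the list's mean per array over the 252 assignments of 10 arrays, whose smallest possible p is 0.00794. Prl, Irgq, Nr4a1, Junb, Pxmp4, Lysmd4 and Abcg2 are named outside the rule that follows, after the values were seen. The other genes named below were set by rule before the data were examined: up to 12 higher and 12 lower genes past the threshold, filled up with the smallest unadjusted p where fewer passed, up to 4 members with the smallest p from each list described, and 11 genes fixed by name. Of those 11, Npas4 and Agrp are not named on the array here. Predicted genes whose symbols start with LOC or RGD were passed over.

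The fit was tested on simulated data with the real means and within-group spreads of the 31042 probe sets of the comparison of DMHF with control, 200 of them changed. It recovered 8% of the probe sets shifted by 2 within-group SD, 44% of those shifted by 4, 90% of those shifted by 6 and 98% of those shifted by 8. Camera recovered 3 of 3 lists shifted by 1 SD in data simulated for 14217 independent genes. The number of arrays limits the precision of all values.

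Alternatives were the replicate number as a block, quantile normalization, a common array median, the brighter 15521 probe sets alone, array weights, the mean of the choroid plexus list as a covariate, a trended and robust variance, 1 probe set per gene, other choices of probe set per gene, other list tests, a rank product test, and each array left out in turn. The false discovery rate of the rank product came from 100 draws of random values with the same spread for every probe set, not from permuting the real values. A pseudocount was not needed, because the values were already on a log scale. No column of the table was left unused.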

Results

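Gene expression was measured in the right side of the brain of 10 male Wistar rats after 5 min of breathing vapor over water or over DMHF. Per the design text, 5 mL of liquid stood in a flask through which air was pumped, the rats then waited 10 min before they were killed, and inhalation preceded the dark period. The design holds a single comparison, DMHF (n = 5) against control (n = 5), and asks which brain transcripts differ shortly after the odor is inhaled. Array medians lay at 7.24 on the deposited log2 scale and differed by at most 15.2 millionths of a log2 unit. The files held 0 pairs of identical arrays. The leading principal component of the standardised values carried 21.3% of the variance and did not separate the groups (exact two-sided permutation test, p = 0.563), nor did the next component with 14.9% (exact p = 0.190).

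No transcript passed the test for a difference between rats that inhaled DMHF and control rats. Of 31042 probe sets, 0 were higher and 0 lower at an adjusted p under 0.05 by limma, and the smallest adjusted p was 0.698. At an unadjusted p under 0.05, limma listed 1002 probe sets higher and 698 lower in DMHF, 1700 in all or 5.48%, where 1552 would be listed by chance. The split differed with the scaling, with 450 higher and 154 lower after quantile normalization and 208 higher and 333 lower with a common array median. Quantile normalization left only 10076 probe sets to test. The array medians differed by more than the SD of most probe sets, so a common median adds an offset to most. The values of all 5 DMHF rats lay outside the range of the 5 control rats for 269 probe sets, 166 above and 103 below, and chance gives 246 (0.794%). A rank product test on the same values, in contrast, called 214 probe sets higher and 449 lower at a false discovery rate under 0.05, 21 of them in both directions. Data simulated without any change but with the real spread of each probe set gave 588 rank product calls and 0 limma calls. In simulated data with 200 changed probe sets, limma called 90% of those changed by 6 within-group SD and 8% of those changed by 2 SD. With fewer changed probe sets the adjustment is stricter, so this is no bound for the real data. In the real data Cbarp at 7.00 SD was not called. Its moderated SE of 0.256 millionths exceeded the SD of either group (0.226 and 0.245), and its moderated t of 6.45 was close to the 6.48 of Itih4 at 3.93 SD.

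**Figure D1:**
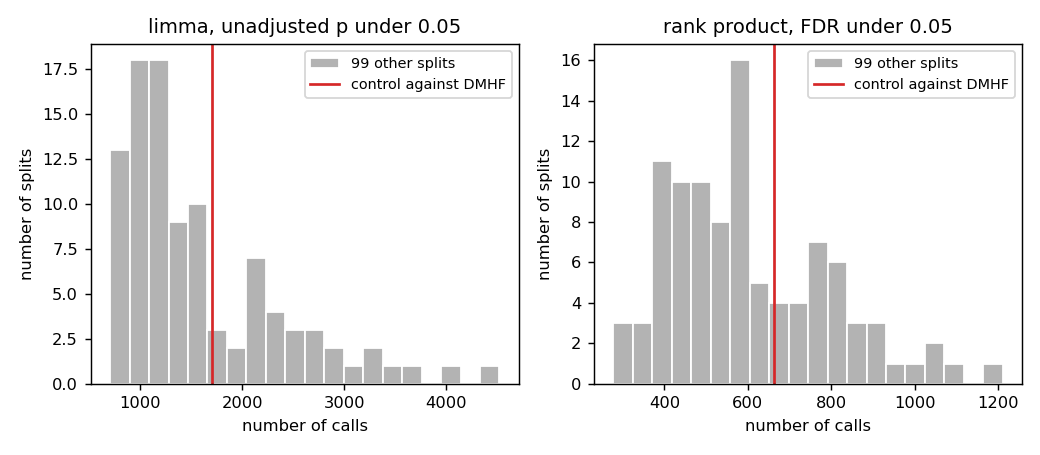
Number of calls (horizontal axes) over 99 other splits of the 10 arrays into 5 and 5 (vertical axes, number of splits), for limma at an unadjusted p under 0.05 and for the rank product at a false discovery rate under 0.05. The line marks control against DMHF, at 1700 and 663 calls, within the range of the other splits, 703 to 4523 and 278 to 1211.

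The genes with the smallest p values higher in DMHF were Itih4, an acute-phase plasma protein, Cbarp, a regulator of voltage-gated calcium channels, Cdca2, Gpx6, a glutathione peroxidase, Drd5, a dopamine receptor, Prrt1, a partner of AMPA-type glutamate receptors, Gp2, Star, which moves cholesterol into mitochondria for steroid synthesis, Ilvbl, Panx3, Sfmbt2 and Lsmem2. None passed the test (limma adjusted p = 0.698 for each). Itih4 differed by 10.7 millionths of a log2 unit (SE 1.65), or 3.93 within-group SD. Drd5 differed by 3.24 millionths (SE 0.567), or 3.70 SD, and was the single member of the dopamine and noradrenaline list with an adjusted p under 0.05 when adjusted over the list alone. Cbarp differed by 1.65 millionths (SE 0.256), or 7.00 SD. For each of these 12 genes, which were picked by their p, all 5 DMHF rats lay above all 5 control rats. Apart from Cbarp and Prrt1, their means lay below the array median of 7.24, with Itih4 at 5.97 and Drd5 at 6.47, where the lowest deposited value was 5.25. Whether probe sets this dim measure a transcript of the brain was not tested. Star was measured by a further probe set whose difference had the other sign, -1.91 millionths (unadjusted p = 0.349), and the brightest probe set of Prrt1 differed by 0.082, or 0.184 SD (unadjusted p = 0.816).

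The genes with the smallest p values lower in DMHF were Rpa1, a single-stranded DNA-binding protein, Luc7l3, a splicing factor, Cnr1, the cannabinoid receptor of neurons, Foxp1, a transcription factor, Angptl4, an inhibitor of lipoprotein lipase, Rbsn, an endosomal protein, Ash1l, a histone methyltransferase, Ppih, a spliceosomal cyclophilin, Cntnap2, a neuronal adhesion protein, Rnpc3, a protein of the minor spliceosome, Chd4, a chromatin remodeller, and Mtmr11. None passed the test (limma adjusted p = 0.698 for each). Rpa1 differed by -12.7 millionths (SE 1.92), or -3.99 within-group SD, and Cnr1 by -41.7 millionths (SE 7.37), or -3.41 SD. The brighter probe set of Cnr1, at a mean of 11.49 against 7.77, was lower too, by -0.072 millionths, or -1.38 SD (unadjusted p = 0.746 by limma). Its moderated SE of 0.215 exceeded the SD of either group (0.0614 in control and 0.0412 in DMHF), so this p does not reflect its own spread. Luc7l3 and Rnpc3 had a negative difference on all 3 of their probe sets, while the other probe sets of Cntnap2, Chd4, Ash1l and Rbsn went both ways. After quantile normalization the named Rnpc3 probe set stood at 58.4, outside its deposited values on all 10 arrays (-16.8 to 3.89 from the control mean). That value is thus no measure of its deposited difference. The other probe set of Ppih had the other sign, 8.60 millionths (unadjusted p = 0.224), and the brightest of Foxp1 differed by -0.0768 (unadjusted p = 0.974).

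Of the 38 gene lists, 4 passed camera with its preset correlation, each at an adjusted p of 0.0331: the pituitary, choroid plexus and ependyma lists were shifted to higher values in DMHF and the glucocorticoid-responsive list to lower values. No list passed with an estimated correlation (adjusted p = 0.193 for each of these 4), by fry (smallest adjusted p = 0.366) or by the exact permutation test of list means (smallest adjusted p = 0.804). The exact test could hardly pass any list. Its smallest possible p of 0.00794, adjusted over 38 lists, stays above 0.05 unless several lists reach it together, so its failure says little. At an unadjusted p under 0.05, camera with an estimated correlation listed 9 lists, fry 4 and the exact test 2. With control replicate 3 left out, or control replicate 5, 0 lists passed the preset camera test. Without control replicate 1 there were 8, without DMHF replicate 3 there were 7, and without DMHF replicate 1, 4 or 5 there were 2. No member of any list passed limma over all probe sets.

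**Figure D2:**
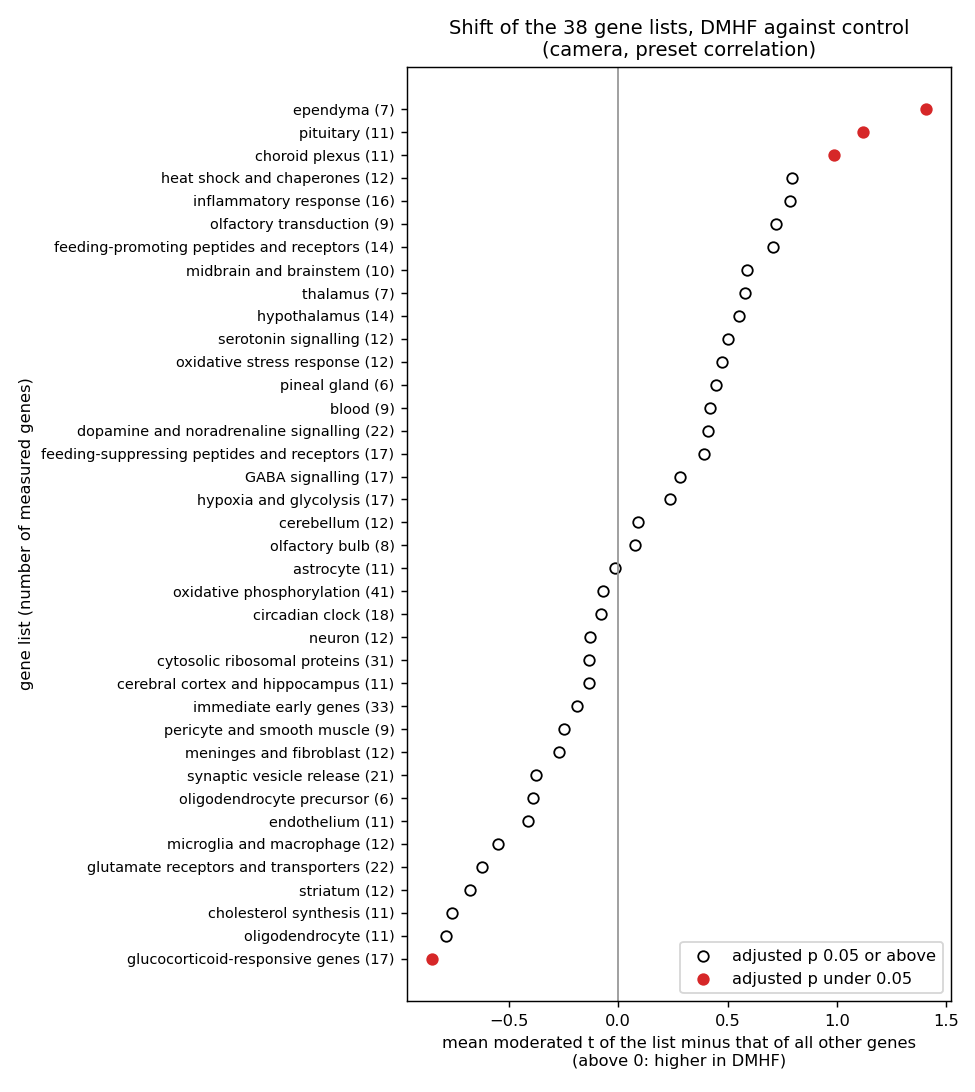
Shift of each of the 38 gene lists, as the mean moderated t of its genes minus that of all other genes (horizontal axis, no unit), with the number of measured genes in parentheses. Filled points mark the 4 lists with a camera adjusted p under 0.05 at the preset correlation, 3 shifted higher in DMHF and 1 lower.

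In the pituitary list, 10 of 11 measured genes were nominally higher in DMHF, and the subunits of thyroid-stimulating hormone had the smallest p values. Cga, the alpha subunit shared by the glycoprotein hormones, differed by 5397 millionths of a log2 unit (SE 1259), or 2.58 within-group SD. All 5 DMHF rats lay above all 5 control rats. Its limma adjusted p was 0.730 over all probe sets, and it passed when adjusted over the list alone. Tshb, the beta subunit, differed by 5287 millionths (SE 1608), or 1.98 SD, with an adjusted p of 0.815, and 2 of 5 DMHF rats lay above all controls. The means of Tshb and Cga were 5.76 and 6.45 on the deposited scale, below the array median of 7.24. Growth hormone (Gh1), prolactin (Prl) and the precursor of corticotropin (Pomc), abundant products of the anterior lobe, differed by 3.74, 0.434 and -0.379 millionths (unadjusted p = 0.0899, 0.949 and 0.510 by limma). Without Tshb and Cga the shift in mean moderated t against other genes was 0.546 in place of 1.12 (adjusted p = 0.323), but the pair was picked after seeing the data, and leaving out the members with the smallest p weakens any shifted list. Over its 22 alternatives the adjusted p of the pituitary list ranged from 5.41e-05 to 0.804.

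**Figure D3:**
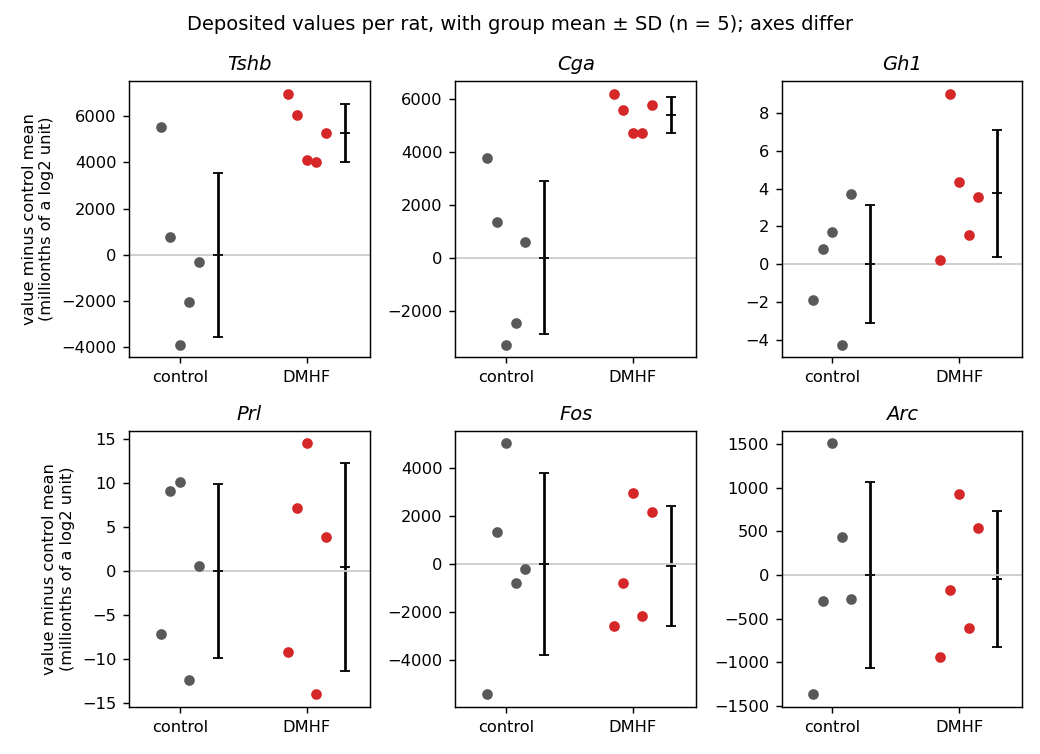
Deposited values of single rats for 6 genes, as the difference from the control mean in millionths of a log2 unit (vertical axes, which differ between panels), with group mean and SD (n = 5) beside the points. Cga of DMHF rats lay between 4708 and 6207 and that of control rats between -3287 and 3777, whereas the groups overlapped for Fos and Arc.

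All 11 measured genes of the choroid plexus list and all 7 of the ependyma list were nominally higher in DMHF, with 0 members past the test in either list. In the choroid plexus list, Folr1, a folate receptor, differed by 41.5 millionths (SE 17.4), and Ttr, the thyroid hormone carrier of the cerebrospinal fluid, by 61.3 millionths (SE 44.4). Sostdc1 (370 millionths, SE 286) and F5 (169 millionths, SE 132) followed. With single arrays left out Ttr ranged from 36.3 to 82.0, Sostdc1 from 196 to 515 and F5 from 85.1 to 231 millionths. In the ependyma list, Foxj1, the regulator of motile cilia, differed by 14.2 millionths (SE 6.20), Tmem212 by 42.1 (SE 18.3), Drc12 by 20.2 (SE 10.2) and Tekt1, a ciliary protein, by 22.4 (SE 13.2). With the mean of the choroid plexus list as a covariate, the ependyma list no longer passed camera (adjusted p = 0.376) and neither did the glucocorticoid-responsive list (adjusted p = 0.539), while 3 lists passed: pituitary higher (0.019) and meninges and fibroblast (0.011, range 0.011 to 1 over 23 alternatives, 2 of them in the other direction) and oligodendrocyte (0.019) lower. These 3 passed at the preset correlation. With an estimated correlation and no covariate, the adjusted p of camera was 0.667 for meninges and fibroblast and 0.193 for oligodendrocyte and pituitary. Over all alternatives adjusted p ranged from 1.17e-08 to 0.804 for ependyma, from 1.38e-07 to 0.936 for choroid plexus and from 0.000503 to 0.936 for the glucocorticoid-responsive list.

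Of the 17 measured glucocorticoid-responsive genes, 15 were nominally lower in DMHF and 0 passed the test. The smallest p values in that list belonged to Nr3c2, the mineralocorticoid receptor (-0.871 millionths, SE 0.461), the metallothioneins Mt2A (-53.4, SE 29.4) and Mt1 (-2.65, SE 1.76, but 40.5 after quantile normalization), and Nfkbia, an inhibitor of NF-kappa-B (-147, SE 98.9). None of the 4 differed by more than 1.28 within-group SD in size, where the SD is that between rats of a group. The choroid plexus and ependyma lists shifted in the same comparison, by 0.988 and 1.41 in mean moderated t against other genes, and the glucocorticoid-responsive list by -0.852. With single arrays left out these shifts ranged from 0.575 to 1.37, from 0.969 to 1.98 and from -1.27 to -0.509, in that order.

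Immediate early genes, whose transcripts rise within minutes of neuronal activity, did not pass as a list with all arrays. Of 33 measured members, 12 were nominally higher and 21 lower, 0 passed the test, and camera gave an adjusted p of 0.535. At the preset correlation the list passed, shifted lower, without control replicate 1 (0.0172) or DMHF replicate 3 (0.0314). Its adjusted p ranged from 0.0172 to 1 over 23 alternatives, 5 of them in the other direction. Its members correlated at 0.439 within groups, and with an estimated correlation and all arrays camera gave an adjusted p of 0.807. Fos differed by -73.0 millionths (SE 1930), Arc by -50.0 (SE 559) and Egr1 by 50.4 (SE 195), each far less than the spread between rats. The SD of Fos was 3776 millionths among control rats and 2512 among DMHF rats. The signs of the Fos, Egr1 and Arc differences changed with single arrays left out, that of Fos from -1425 without control replicate 1 to 1185 without control replicate 3. The members with the smallest p, Fosl2 (2.99, SE 1.75), Zfp36 (-1.56, SE 1.03), Egr3 (1.89, SE 1.29) and Homer1 (-6.36, SE 6.26), lay near or within 1 within-group SD of 0. Their size also depended on single arrays, with ranges of 1.40 to 3.90, -2.12 to -0.963, 0.972 to 2.43 and -9.34 to -1.53 in that order.

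Peptides and receptors that promote feeding were nominally higher in DMHF for 9 of 14 measured genes, and the list did not pass camera (adjusted p = 0.123). Npw, neuropeptide W, differed by 18.8 millionths (SE 5.52), or 2.05 within-group SD (limma adjusted p = 0.802). Hcrtr1, an orexin receptor, differed by 5.20 (SE 2.12), Pmch, the precursor of melanin-concentrating hormone, by 303 (SE 137), Ghsr, the ghrelin receptor, by 4.38 (SE 2.02), and Hcrt, the orexin precursor, by 61.7 (SE 36.0). Npy differed by -1.98 (SE 1.51). Genes that suppress feeding were nominally higher for 12 of 17 (camera adjusted p = 0.372), with Nmu at 2.47 (SE 0.927), Cartpt at 911 (SE 461), Glp1r at 2.96 (SE 1.74) and Oxt at 757 (SE 662). Pomc stood at -0.379 (SE 0.552). Th, the rate-limiting enzyme of dopamine synthesis, differed by -1.92 (SE 8.54).

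Among lists tied to odor and transmission, olfactory transduction had 8 of 9 members nominally higher (camera adjusted p = 0.160), with Cngb1 at 1.35 (SE 0.685), Gnal at 2.92 (SE 1.84) and Ano2 at 1.91 (SE 1.39), and Gng13 at -0.606 (SE 0.439). Glutamate receptors and transporters had 13 of 22 members lower (adjusted p = 0.0951, and 0.0256 without DMHF replicate 3, range 0.0195 to 0.936), with the NMDA receptor subunits Grin2a at -48.5 (SE 18.4) and Grin2b at -9.15 (SE 4.12). A further probe set of Grin2a differed by -254 (SE 72.8, limma adjusted p = 0.787). Of the same list, Grm3 stood at -2.12 (SE 1.01) and Grik4 at -2.29 (SE 1.10). The inflammatory list had 12 of 16 members higher (adjusted p = 0.0822), and passed without control replicate 1 (0.0464) or control replicate 2 (0.0237), with a range of 0.0237 to 0.936 over 22 alternatives, 2 of them in the other direction. Its chemokine Ccl3 differed by 7.56 (SE 1.97), or 2.32 within-group SD, with all 5 DMHF rats above all controls and a limma adjusted p of 0.738. Socs3 (1.89, SE 0.902), Lcn2 (5.00, SE 2.55) and Icam1 (3.02, SE 1.63) followed. None of these members passed the test.

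Heat shock genes and chaperones were nominally higher for 11 of 12 members (camera adjusted p = 0.0951), and the list passed without control replicate 1 (0.0102), control replicate 4 (0.0355) or DMHF replicate 3 (0.0256), with a range of 0.0102 to 1 over its alternatives. Hspa1a, an inducible heat shock protein, differed by 11.7 millionths (SE 3.80), or 1.86 within-group SD, and Dnajb1 by 0.850 (SE 0.508), Hspe1 by 0.432 (SE 0.375) and Hsp90ab1 by 0.414 (SE 0.367). All 12 members of the striatum list were nominally lower (adjusted p = 0.123), and it passed without control replicate 1 (0.0172), DMHF replicate 2 (0.0146) or DMHF replicate 3 (0.0256), with a range of 0.0146 to 0.936. Among them were Rgs9 (-3.61, SE 3.10), the dopamine receptors Drd2 (-7.92, SE 8.36) and Drd1 (-10.1, SE 13.0) and their signalling partner Ppp1r1b (-9.17, SE 12.4). After quantile normalization Rgs9 stood at 46.0, outside its deposited values on all 10 arrays (-8.05 to 7.46 from the control mean). That value is thus no measure of its deposited difference. A further probe set of Drd1 had the other sign, 0.531 (SE 1.25). With single arrays left out Drd2 ranged from -13.6 to -3.59, Drd1 from -17.8 to -2.38 and Ppp1r1b from -15.6 to -3.45. In the hypothalamus list 9 of 14 members were nominally higher (adjusted p = 0.245), led by Hdc, the enzyme that makes histamine (6.43, SE 2.33), with Pmch and Hcrt as above and Ghrh at 0.933 (SE 0.810). The passes of the heat shock and striatum lists are at the preset correlation. With an estimated correlation and all arrays camera gave an adjusted p of 0.193 for both lists. None of the members named in this paragraph passed the test either.

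The other functional lists did not pass camera with all arrays either. Adjusted p was 0.104 for cholesterol synthesis (0.0307, lower, without DMHF replicate 1, range 0.0307 to 1), 0.310 for serotonin signalling, 0.387 each for dopamine and noradrenaline signalling, synaptic vesicle release and the oxidative stress response, 0.488 for GABA signalling, 0.539 for hypoxia and glycolysis, 0.688 for cytosolic ribosomal proteins, 0.830 for oxidative phosphorylation and 0.851 for the circadian clock. Of the lists for cell types and regions, the oligodendrocyte list gave 0.0951 (0.0149, lower, without DMHF replicate 4, range 0.0149 to 0.936), microglia and macrophage 0.295, midbrain and brainstem 0.310, thalamus 0.346, endothelium 0.387, blood 0.438, pineal gland 0.485, oligodendrocyte precursor 0.535, meninges and fibroblast 0.539, and pericyte and smooth muscle 0.655. Neuron, cerebral cortex and hippocampus, and cerebellum each gave 0.830, olfactory bulb 0.851 and astrocyte 0.920. The mean, median and camera direction differed in sign for the circadian clock, oxidative phosphorylation, ribosomal protein, neuron and astrocyte lists, all with shifts near 0. The mean of the deposited values was lower in DMHF for the inflammatory list, -7.04 millionths, and the cerebellum list, -0.536, and higher for immediate early genes, 6.84, the circadian clock, 3.69, and neurons, 2.77, against the direction of camera. That mean is weighted toward members of wide deposited spread. With each gene standardised over the arrays, the list mean went with camera for the inflammatory (0.459), cerebellum (0.115) and immediate early (-0.0614) lists. It still went against camera for the circadian clock (0.0299) and neurons (0.0224).

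The control probe sets were read for signs of RNA quality. A 3' minus 5' difference combines different probe sets, whose deposited values are not comparable, so neither a difference nor its absence settles RNA quality here. The 3' minus 5' difference of hexokinase was higher in DMHF by 13.4 millionths (exact two-sided permutation p = 0.0317, adjusted p = 0.159 over 5 measures), while that of beta-actin (exact p = 0.206) and GAPDH (exact p = 0.683) and the spike-in controls (exact p = 0.286 and 0.214) did not reach an exact p under 0.05, and none of the 5 measures passed after adjustment.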

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

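The tests in this part that were chosen only after the result was seen are the search for single rats, the other splits of the arrays, the share of calls among probe sets of wide spread, the correlations, and the contrasts of Tshb and Cga with other pituitary and hypothalamic genes. In 8 of 170 groups of 5 rats examined, a single rat stood apart from the other 4 of its group by more than Dixon's critical value of 0.71, given as the gap to the nearest rat over the group's range. Chance alone gives about 1 in 20 groups, or 8.5. The genes were Mt1 in DMHF replicate 5 (0.788), Homer1 in control replicate 4 (0.723), Hspa1a in control replicate 3 (0.767, the lowest of its group), Dnajb1 in DMHF replicate 3 (0.771), Hsp90ab1 in DMHF replicate 1 (0.755), Ghrh in control replicate 3 (0.789), Drd1 in control replicate 5 (0.782) and Pomc in control replicate 4 (0.765, the lowest of its group).

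The rank product made 663 calls on 642 probe sets, 21 of them called in both directions, where limma called 0 and listed 1700 at an unadjusted p under 0.05. Of the 642, which include Cga, Tshb, Cartpt, Pmch, Oxt and, in both directions, Fos, 84.1% lay among the 5% of probe sets with the widest spread between rats of a group. A candidate explanation is that the deposited scale, far wider for some probe sets than for others, lets those fill the top ranks whatever the groups. Data simulated without any change gave 588 rank product calls with the real spreads and 0 with equal spreads. Unequal spreads alone can thus yield calls in such numbers. Of 100 splits of the 10 arrays, the real one included, 32 gave at least 663 calls, with 1211 as the highest other, and chance cannot be excluded. Limma tested each of the 642 for an effect of DMHF and none passed (smallest adjusted p = 0.698). With 5 rats per group this does not exclude an effect on single genes.

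Tshb and Cga, picked for their small p in the pituitary list, were higher in DMHF by 2.28 within-group SD for their mean, and neither passed limma over all probe sets. Anterior pituitary tissue left on the DMHF samples would bring its abundant transcripts Gh1, Prl and Pomc, which were higher by 0.248 SD (exact p = 0.675), and the pair exceeded them by 2.03 SD (exact p = 0.0317), but picking the pair by its difference favours this contrast, so it excludes nothing and the explanation stays open. Over the 10 arrays Tshb followed Cga (Pearson r = 0.975, permutation p = 6e-05, adjusted p = 0.000245 over 7 relations, Spearman rho = 0.891, permutation p = 0.00119, r = 0.94 without the 2 arrays farthest from the median, and r = 0.955 with group means taken out, permutation p = 0.00032), while its relation did not pass the test with Gh1 (r = 0.329, permutation p = 0.356, adjusted p = 0.415, rho = 0.115, permutation p = 0.76, r = 0.0302 without 2 arrays) or Prl (r = -0.146, permutation p = 0.684, adjusted p = 0.684, rho = -0.127, permutation p = 0.736, r = -0.277 without 2 arrays). With group means taken out, r of Tshb was -0.128 with Gh1 (permutation within groups, p = 0.763) and -0.242 with Prl (permutation p = 0.531). Gh1 and Prl had low means of 6.38 and 6.25, so these relations do not decide about anterior pituitary tissue. More of the hypothalamic base, on which the pars tuberalis makes Tshb and Cga, may have stayed on the DMHF samples. The hypothalamus list without Pomc was higher by 0.455 SD (exact p = 0.119). That list was made of hypothalamic genes, not those of the pars tuberalis, so it cannot decide this. Tshb and Cga were each highest in replicate 1 of both groups (Tshb at 5521 and 6993 millionths from the control mean, Cga at 3777 and 6207). Their relation may thus also follow the replicate number, which was not tested. An effect of DMHF was tested by limma, which neither gene passed (adjusted p = 0.815 for Tshb and 0.730 for Cga). With 5 rats per group this does not exclude it.

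The pituitary, choroid plexus, ependyma and glucocorticoid-responsive lists, the 4 lists past camera, did not stand out from other groupings of the same rats. Of 100 splits, 61 gave at least 4 lists, with 14 as the highest other, and chance cannot be excluded. A candidate explanation is that members of a list vary together between rats: the mean correlation of members within groups was 0.229, 0.526, 0.511 and 0.208 in that order, against the preset 0.01, and 0 of the 4 lists passed with an estimated correlation. A difference in dissection between rats stays open, as untested. For an effect of DMHF, the 4 lists passed camera at the preset correlation but none of the other list tests, so it stays open too.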

How the results depend on the processing

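The standardised list means and the pituitary list without Tshb and Cga were chosen after seeing the data, and all other alternatives here before. The cause of the changes below was not tested except where stated. The count of changed probe sets, 0 by limma with 1700 at an unadjusted p under 0.05, became 13 after quantile normalization and 642 by rank product (663 calls, 21 probe sets being called both ways), and was 0 under the other alternatives that use all arrays. The 13 were all constant within a group. Quantile normalization left 20966 of 31042 probe sets without any variation and 10076 to test. With each array left out in turn the count ranged from 0 to 1, the single call being Irgq without DMHF replicate 2 (13.95 millionths, SE 1.06, limma adjusted p = 0.0386, and 0.855 with all arrays), chosen after its values were seen.

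The probe sets at an unadjusted p under 0.05 (1002 higher and 698 lower, 58.9% higher) became 604 after quantile normalization (450 higher, 154 lower, 74.5% higher), 541 with a common array median (208 and 333, 38.4% higher), 700 among the brighter 15521 probe sets (287 and 413) and 728 with 1 probe set per gene (450 and 278). Fewer probe sets were tested in the last 2 and after quantile normalization. The array medians differed by up to 15.2 millionths, more than the SD of most probe sets, so setting them equal adds an offset to most. They ranged from 1319 to 2156 with each array left out.

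The number of lists past camera, 4, became 0 after quantile normalization, 11 with a common median, 1 among the brighter probe sets, 3 with the choroid plexus mean as a covariate, 2 with array weights, 2 with the most variable probe set per gene and 2 with the mean of a gene's probe sets. It was 0 with an estimated correlation, 0 by fry, 0 by the exact permutation of list means and 0 by that of standardised list means, and ranged from 0 (without control replicate 3 or 5) to 8 (without control replicate 1). The lists added with a common median were oligodendrocyte, striatum, glutamate, and microglia and macrophage lower, and feeding-promoting, thalamus and hypothalamus higher, of which microglia and macrophage and thalamus each had the other direction in 1 alternative. The 4 lists kept their direction in all of these alternatives in which they could be tested.

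Of 1370 values of the 81 named genes under alternatives, 25 had the other sign, in 10 probe sets, and no gene passed except 23 by rank product. The 1370 include values that cannot change sign, since the rank product, the replicate block and the trended and robust variance leave the difference as it is. After quantile normalization Rnpc3 stood at 58.351 millionths, Mt1 at 40.533, Rgs9 at 45.996 and Arc at 93.905. Quantile normalization moves a value in steps between neighbouring ranks, and these steps exceeded the spread of most probe sets. The values of Rnpc3, Mt1 and Rgs9 lay outside their deposited values on all 10 arrays. Their signs, counted among the 25, thus say nothing about the deposited difference. With the choroid plexus mean as a covariate Sostdc1 stood at -29.857, F5 at -5.3399, Oxt at -126.87, Fos at 1571.8 and Arc at 463.55. With array weights Fos stood at 82.375. With each array left out Fos ranged from -1425.2 to 1185, Egr1 from -66.137 to 158.5, Arc from -391.12 to 326.29 and Th from -8.2364 to 2.3645.

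The labels do not say that replicate numbers pair the rats, and not every correlation of same-numbered deviations was over 0.1 (0.214, 0.0329, 0.273, 0.0856 and 0.0288), so they were not treated as pairs. All 5 were above 0, though, 6 of 10 arrays correlated best with their own number where chance gives 2, and 2 of the 120 pairings, the real one included, had a mean correlation of 0.127 or more (exact one-sided p = 0.0167, a test chosen after seeing the data), a hint of pairing from the data. With the replicate number as a block, 0 probe sets passed, 2217 had an unadjusted p under 0.05 and 5 lists passed camera, the added one being oligodendrocyte, lower (0.0266, range 0.0149 to 0.936). The pseudocount alternative was not run, because the values are on a log scale. Signal over background was not given in the table used here.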

Other observations

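The relations and counts in this part were tested only after the values were seen. Immediate early genes varied together between rats of both groups. Over the 10 arrays Fos followed Arc (Pearson r = 0.923, permutation p = 0.00022, Spearman rho = 0.891, permutation p = 0.00111), Nr4a1 (r = 0.953, permutation p = 0.00016, rho = 0.915, permutation p = 0.00064), Egr1 (r = 0.92, permutation p = 2e-04, rho = 0.855, permutation p = 0.00301) and Junb (r = 0.955, permutation p = 7e-05, rho = 0.939, permutation p = 0.00024). Without the 2 arrays farthest from the median of Fos, r was 0.806, 0.857, 0.852 and 0.885. Adjusted over 7 relations, the permutation p of r was at most 0.000308 for these 4. With the group means taken out, r was 0.923, 0.954, 0.925 and 0.956 (permutation within groups, adjusted p at most 0.00428) and rho 0.879, 0.891, 0.891 and 0.915. Fos was lowest in replicate 1 of both groups (-5409 millionths from the control mean in control, -2553 in DMHF) and highest in replicate 3 (5032 and 2976). The pattern thus also follows the replicate number, for which a hint of pairing is given above. A hypothesis is an activity-dependent response that differs between rats whatever they inhaled, since Fos and Arc were high in the same rats. Differences in handling, in time to freezing, in the share of some region or shared by rats of the same number would leave the same trace. None of these was tested.

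Some of the probe sets with the widest deposited spread, a ranking that depends on the deposited scale, differed between rats in steps. Pxmp4, a peroxisomal membrane protein, lay between -39458 and -36587 millionths from its mean in DMHF replicates 2, 3 and 4, between 755 and 6064 in control replicates 2, 3 and 4, and between 25471 and 27333 in replicates 1 and 5 of both groups. Its steps thus also follow the replicate number, and a link to that number was not tested. Lysmd4 lay between -29060 and -24388 in 5 rats, 2 of them controls, between 13393 and 20681 in 3 and at 41266 and 42626 in 2. Of the 10 most variable named probe sets, 6 had a largest gap between arrays above the 95th percentile of all probe sets, 48.9% of the range, where chance gives 0.5, and Tshb, Cga, Fos and Abcg2 had smaller gaps. A candidate explanation is expression variants that some rats of the stock carry, which is a hypothesis and was not tested on DNA.

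Some groupings of the rats that cross the treatment gave more differences than the treatment did. Of 100 splits of the 10 arrays, the real one included, 31 gave at least 1700 probe sets at an unadjusted p under 0.05, and chance cannot be excluded for that count. For the 0 past an adjusted p the splits test nothing, since all 100 must reach 0. The highest other counts were 4523, for control replicates 1, 2 and 4 with DMHF replicates 1 and 5 against the rest, and 18 past an adjusted p, for control replicates 1 and 2 with DMHF replicates 1, 4 and 5. These are the extremes of 99 overlapping splits, so a structure among the rats that the labels do not name may lie behind them but was not tested.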
